A study of Callithrix jacchus with 4 samples.

How the data were processed

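RNA-seq was carried out on brain tissue of common marmosets (Callithrix jacchus) at postnatal day 5, with 2 libraries from wild-type animals and 2 from FMR1 mutant animals made with CRISPR/Cas9. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase I, selected for poly(A) and made into libraries with a directional kit, which keeps the strand of each transcript. The submitters' processing notes name Trimmomatic 0.38 and STAR 2.7.10a. The counting tool, genome build, annotation and strand setting are not given in the sources used here. The authors deposited a table of whole-number counts per gene, with no normalization, for 35205 genes in the 4 libraries. Of its rows, 17496 carry a gene symbol and 17709 a bare LOC identifier. Each column was assigned to its library by the name in the labels.

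Total counts were 13256200 and 12331639 in wild-type replicates 1 and 2, and 13153036 and 13455702 in FMR1 mutant replicates 1 and 2. Depth was thus similar in both groups. Counting error weighs most on genes of low CPM, the unit of counts scaled by library size. Counting intervals cover counting error only, since the reads carry no molecular identifiers that are used here. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 7.28 between the wild-type libraries and 6.90 between the mutant libraries over genes with at least 10 counts, so each library was counted as its own replicate. The labels give separate samples but do not say that each came from a separate animal, so p-values measure the spread between these samples. Sex, litter and batch are not given in the labels and could not be entered as covariates.

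Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr at its minimum count of 10 were kept (16956 genes, of which 2981 have a LOC identifier), libraries were scaled by TMM, and groups were compared with the quasi-likelihood test (robust = TRUE) and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. The fit had 2 residual degrees of freedom, and the variance of each gene was moderated across genes with a median of 31.6 prior degrees of freedom. The biological coefficient of variation was 11.4%. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic, and fold changes are mutant over wild-type throughout. Mean CPM is given with its SD over the 2 libraries of a group. Wherever an adjusted p of a gene is printed without another tool's name, it is from this edgeR test with Benjamini-Hochberg adjustment.

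Gene lists were chosen before the data were examined: partners and target mRNAs of FMRP, the protein made from FMR1, immediate early genes, synaptic and channel genes, markers of neurons, glia, vessels, blood, choroid plexus, meninges and other brain regions, and genes of growth, energy, sterol and stress pathways. A total of 26 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry, each with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved more than the other genes, and fry whether its genes moved on balance in 1 direction. With so few libraries an estimated correlation is itself imprecise. Camera then also relies on the 2 residual degrees of freedom, which raises its p-values whatever the correlation. A gene in more than 1 list counts in each. Genes were named by a rule fixed at the same time: FMR1 first, then per direction the 12 largest changes past the threshold whose groups did not overlap, with at least 1 CPM in the higher group and a gene symbol, and per list up to 4 passing members by smallest p, or the members with the smallest unadjusted p up to 2 where fewer than 2 passed. A few genes that the rule takes are not reported here by name, though they stay in all tests and counts. Sex-linked genes were counted only as a check of the libraries.

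Before use, the test was run on counts simulated from the real means, library sizes and trended dispersions for the same 16956 genes, 200 of them changed. Genes were drawn independently, with no dispersion of their own, no correlation between genes and no library that stood apart. The false calls in simulated data may therefore understate those in the real counts. It recovered 28.4% of genes changed by 0.5 on the log2 scale, 76.1% of those changed by 1 and 92.4% of those changed by 2, with 6 false calls among 137, and made 0 calls in data with no change. The alternatives were other scalings (RLE and upper quartile), DESeq2 1.42.0, limma-voom, a fit with robust = FALSE, no low-count filter, a mean of at least 1 CPM, the replicate number as a block, each library left out in turn, an adjusted p of 0.1, and leaving out sex-linked genes. DESeq2 was run on all 35205 rows without filterByExpr, so it differs from the main test in gene set as well as in tool. With 1 library left out, the lone library of its group is assumed to vary like the other group. A gene table of the calJac240_pri assembly matched 30938 of the 35205 rows by symbol and was used only to ask which genes neighbour each other. Figures were drawn with matplotlib 3.10.9.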

Results

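The comparison asked how transcript levels in the newborn forebrain differ between marmosets carrying an FMR1 mutation and wild-type marmosets. FMR1 encodes FMRP, an RNA-binding protein that regulates the translation of many neuronal mRNAs and whose loss causes fragile X syndrome. RNA-seq counts from 2 wild-type and 2 FMR1 mutant libraries, all at postnatal day 5, held between 12331639 and 13455702 counts each. They detected between 22601 and 22946 genes. The study's design names cortex, striatum and hippocampus as parts of the forebrain samples. The label of each library gives its tissue only as brain. All library names end in the same letters, Cr, which were not interpreted, so the region behind a library is not known here. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.987 between the wild-type libraries, at r = 0.989 between the mutant libraries and at r = 0.982 to 0.985 between libraries of different groups.

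FMR1 RNA was counted in both mutant libraries at levels that overlapped those of the wild-type libraries. It was counted 1144 and 966 times in wild-type replicates 1 and 2 and 1062 and 1603 times in mutant replicates 1 and 2. Mean abundance was 82.5 ± 5.41 CPM (SD, n = 2) in wild-type and 100.01 ± 26.8 CPM (SD, n = 2) in mutant libraries. The log2 fold change of 0.28 (SE 0.15, 95% interval -0.03 to 0.59) did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.445). The direction rests on mutant replicate 2: without it the log2 fold change was -0.02, and without mutant replicate 1 it was 0.53 (adjusted p = 0.0578). A small CRISPR/Cas9 mutation need not lower the RNA of its gene, so these counts neither check nor contradict the genotype labels. The Y-linked genes KDM5D (275, 364, 376 and 449 counts, wild-type libraries first) and ZFY (217, 237, 222 and 296 counts) were counted in all 4 libraries. Their log2 fold changes of 0.30 (adjusted p = 0.459) and 0.13 (adjusted p = 0.836) did not pass. DDX3Y was counted 0, 0, 0 and 3 times, SRY 1 time in each library and EIF1AY 0 times. Only 5 of the 11 sex-linked genes looked for have a row, and XIST is not among them. These counts therefore leave the sex of the animals open.

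Of the 16956 genes tested, 378 changed, with 112 higher and 266 lower in the mutant libraries. Changes of at least 2-fold were seen in 27 of the higher and 87 of the lower genes. All 378 had groups that did not overlap in CPM, as did 43.1% of the genes tested, where chance alone gives 33.3%. Among the higher genes with a symbol, the largest change was of DPPA4, a chromatin protein of pluripotent cells (40 counts over the mutant libraries against 1 over the wild-type libraries, a ratio of 38.4 with a 95% counting interval of 6.51 to 1556). KASH5, which links meiotic chromosome ends to dynein, was counted 30 against 3 times (ratio 9.61, interval 2.99 to 49.2). These were followed by the cytokine IL32 (log2 fold change 2.48, SE 0.63), the exonuclease TREX2 (2.46, SE 0.65), and MAMDC4 (2.38, SE 0.61). Next came the transcription factor PRDM12 (1.78, SE 0.42), the neutrophil granule protein AZU1 (1.62, SE 0.34) and the hormone receptor PTH2R (1.34, SE 0.34). PLEKHG4B, SPATA5L1 and GBGT1 each rose by 1.17, and REXO4 by 1.02 (adjusted p = 0.0311).

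Among the lower genes with a symbol, the largest decrease was of SKA1, a component of the spindle and kinetochore (36 counts over the wild-type libraries against 2 over the mutant libraries, ratio 18.7, 95% counting interval 4.82 to 161). It was followed by FRMD1 (log2 fold change -3.14, SE 0.67), the macrophage chitinase CHIT1 (-3.08, SE 0.76) and SARDH, a mitochondrial enzyme of sarcosine breakdown (-3.08, SE 0.68). TMEM88B (-2.35), DDX60L (-2.31), the aminoacylase ACY3 (-2.22), the myelin proteolipid MAL (-2.15), the oligodendrocyte-rich protease KLK6 (-2.13), EVI2A (-2.05), PLEKHD1 (-2.03) and coagulation factor F10 (-1.94) followed, with SE between 0.32 for MAL and 0.49 for EVI2A. Most of these genes were of low abundance. Of the 24 genes named by size, 3 (TMEM88B, MAL and KLK6) kept an adjusted p under 0.05 in each of the 4 fits that left out 1 library, and 10 of the 24 passed by DESeq2. The count of changed genes was 163 without mutant replicate 1 (139 of the 378 among them) and 220 without mutant replicate 2 (158 among them). It was 244 by DESeq2, which was run without filterByExpr, and 633 by edgeR without a low-count filter.

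**Figure D1:**
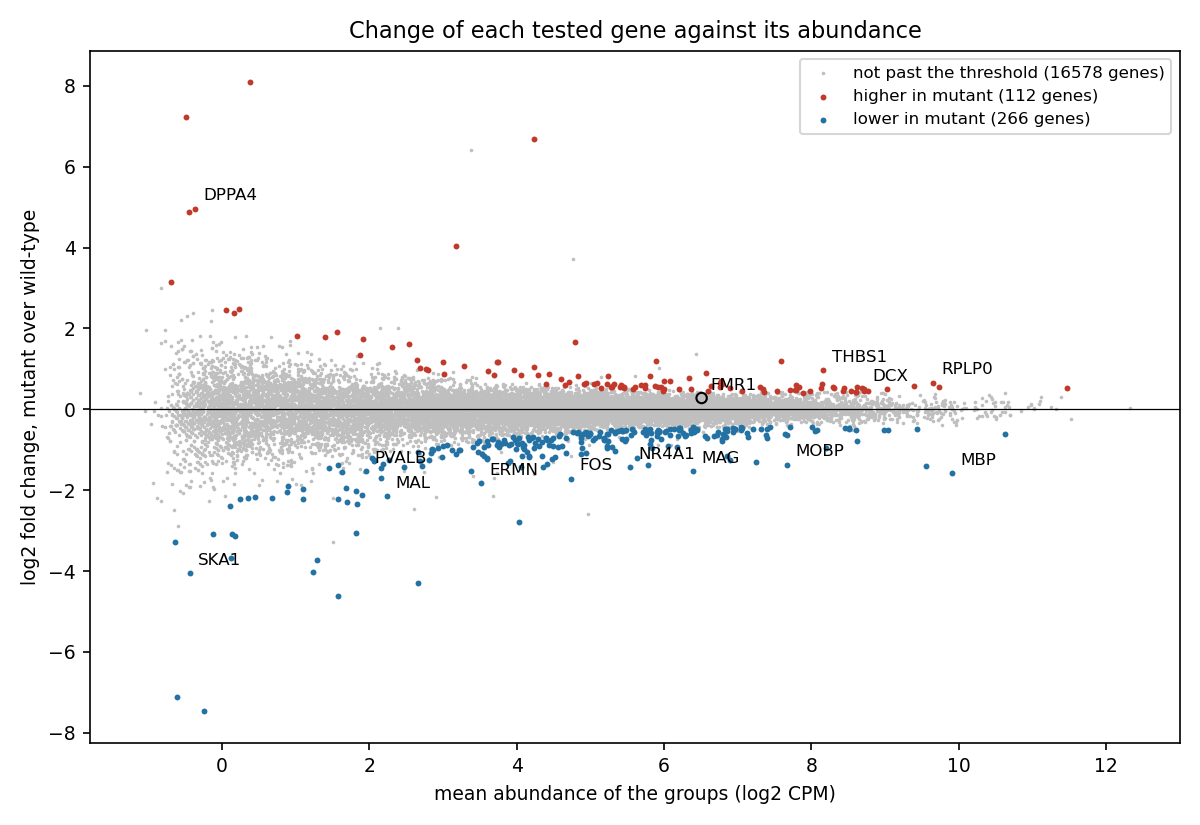
Log2 fold change of mutant over wild-type (vertical axis) against mean abundance in log2 CPM (horizontal axis) for each of the 16956 genes tested, 1 point per gene, with FMR1 circled. The 112 higher genes (red) and 266 lower genes (blue) include abundant genes such as MBP (-1.58) and RPLP0 (0.66), while changes beyond 4 on the log2 scale lie mostly among genes of low abundance.

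Most transcripts of myelin and mature oligodendrocytes, the cells that wrap axons in myelin, were lower in both mutant libraries than in both wild-type libraries. Of 23 list members, 19 fell and 0 rose, and 4 did not pass, TSPAN2, GPR37 and ASPA among them. Adjusted over the list alone, 19 fell as well, and the median log2 fold change was -1.20. MBP, which compacts the myelin sheath, was 1439 ± 43.8 CPM (SD, n = 2) in wild-type and 481 ± 38.5 CPM (SD, n = 2) in mutant libraries. Its log2 fold change was -1.58 (SE 0.11, adjusted p = 1.29e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MAG, an adhesion molecule between myelin and axon, was 125 ± 2.28 against 43.2 ± 0.870 CPM (-1.54, SE 0.13), and MOBP 295 ± 20.7 against 114 ± 3.68 CPM (-1.37, SE 0.12). The list took 0.419% and 0.406% of all counts in the wild-type libraries and 0.173% and 0.167% in the mutant libraries. Camera called the list lower (adjusted p = 6.49e-70), and fry did as well (adjusted p = 0.0427), but with an estimated correlation camera did not (adjusted p = 0.1). Between 15 and 18 of the 19 fallen members kept their call when any 1 library was left out. The number was 18 without wild-type replicate 1, which had the most counts of the thalamic marker TCF7L2 (1272, against 139, 118 and 121 in wild-type replicate 2 and mutant replicates 1 and 2).

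**Figure D2:**
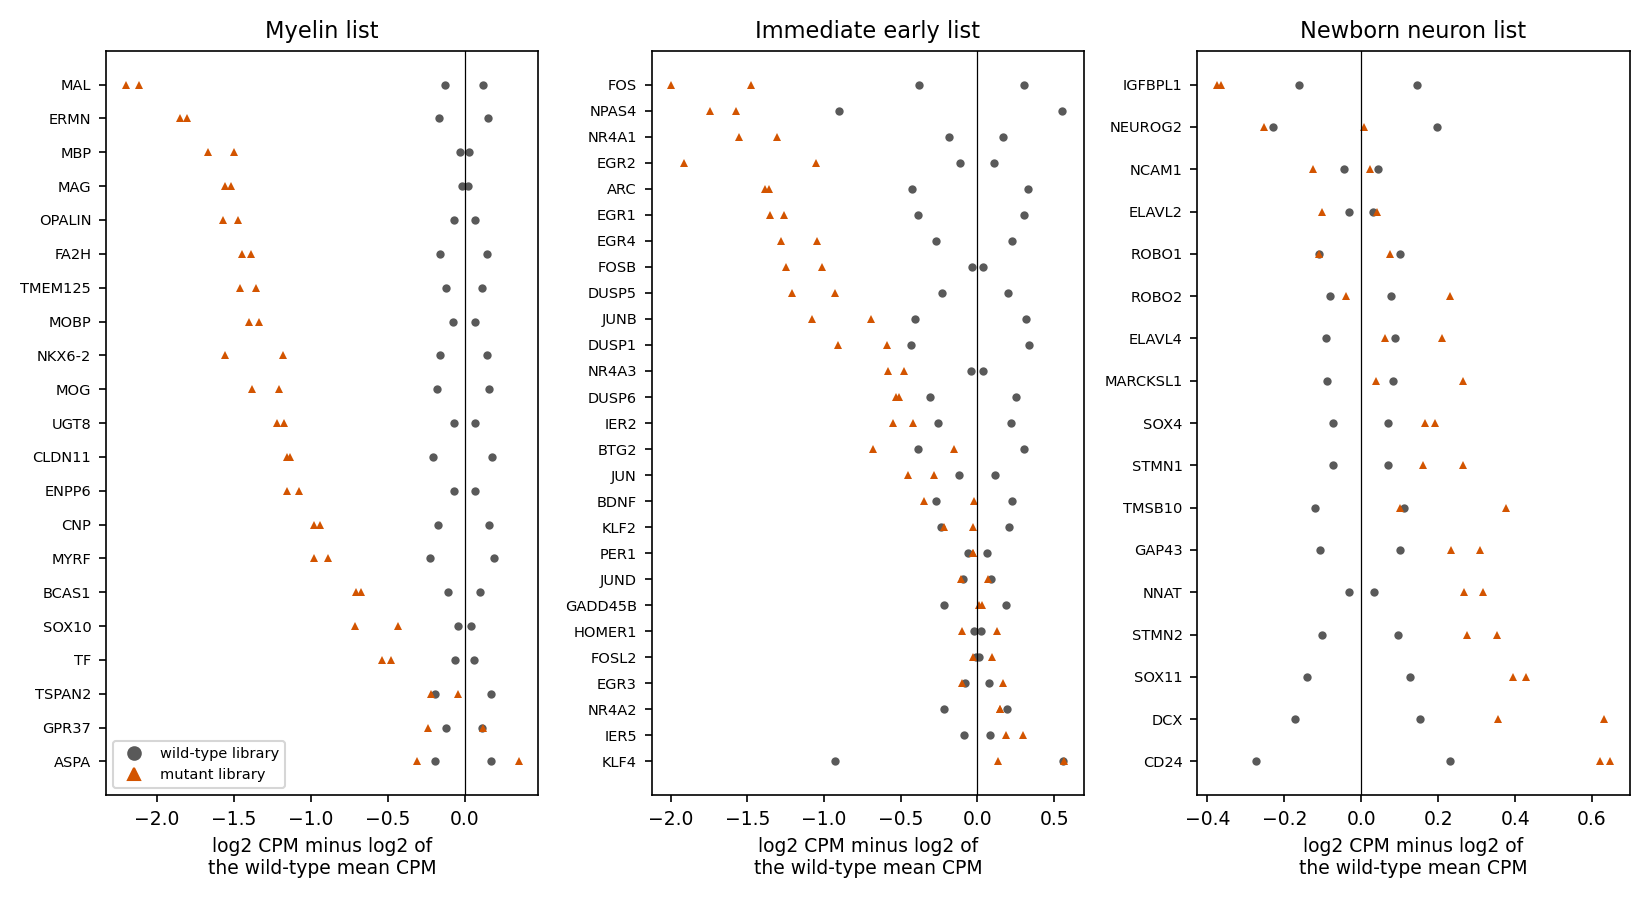
Each library's log2 CPM minus log2 of the wild-type mean CPM (horizontal axis) for tested members of the myelin, immediate early and newborn neuron lists, without genes not reported here (vertical axis, ordered by fold change), with grey circles for the 2 wild-type and orange triangles for the 2 mutant libraries. The fallen myelin genes shown, from MAL (-2.15) to TF (-0.51), have both mutant points left of both wild-type points, and the wild-type points of immediate early genes such as FOS lie far apart.

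Other glial lists were lower by smaller amounts. Among 15 markers of oligodendrocyte precursors, 1 fell and 0 rose (3 fell adjusted over the list alone, median -0.30). It was GPR17, a receptor of cells committed to the lineage (-0.50, SE 0.12, adjusted p = 0.0162), while PDGFRA, the precursor growth factor receptor, did not pass (-0.44, SE 0.13, adjusted p = 0.0554). Among 21 astrocyte markers, 2 fell and 0 rose (8 fell adjusted over the list alone, median -0.23). The glutamate transporter SLC1A2 was 1907 ± 15.3 against 1252 ± 105 CPM (SD, n = 2 each; -0.61, SE 0.11), and the secreted chaperone CLU 599 ± 3.69 against 419 ± 2.30 CPM (-0.51, SE 0.11). Both passed whichever library was left out. Among 17 microglial markers the median was -0.34 (-0.74 without mutant replicate 1 and -0.14 without mutant replicate 2), and 4 fell adjusted over the list alone. Over all genes tested, 3 fell and 0 rose. They were LAPTM5, a lysosomal membrane protein (-0.75, SE 0.15), CSF1R, the receptor on which microglia depend for survival (-0.84, SE 0.19), and the chemokine receptor CX3CR1 (-0.71, SE 0.17). Camera called all 3 lists lower, with adjusted p = 3.14e-04 for precursors, 1.12e-06 for astrocytes and 7.61e-04 for microglia. It called none with an estimated correlation (adjusted p = 0.452, 0.379 and 0.562). GPR17 did not pass without wild-type replicate 2 (adjusted p = 0.0763) or mutant replicate 1 (0.167). Without mutant replicate 2 the microglial list was not called (adjusted p = 0.473) and 0 of its members passed by edgeR. CX3CR1 also did not pass without wild-type replicate 2 (adjusted p = 0.0735) or by DESeq2 (0.083). None of the 21 endothelial and pericyte markers passed by edgeR, DESeq2 or voom, and 0 did adjusted over the list alone (2 were lower at an unadjusted p under 0.05). The median was -0.14 (camera adjusted p = 0.148), with ABCB1 at -0.54 (adjusted p = 0.279) and FLT1 at -0.35 (adjusted p = 0.370). Fry called this list lower (adjusted p = 0.0427).

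Immediate early genes, which neurons switch on within minutes of activity, were mostly lower in the mutant libraries, with 20 of 27 members lower and 7 higher. Of the 27, 6 fell and 0 rose over all genes tested, and 14 fell adjusted over the list alone, with a median of -0.48. The nuclear receptor NR4A1 was 67.6 ± 11.7 CPM (SD, n = 2) in wild-type and 25.1 ± 3.06 CPM (SD, n = 2) in mutant libraries. Its log2 fold change was -1.43 (SE 0.15, adjusted p = 9.20e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The transcription factors EGR4 (-1.16, SE 0.19), FOS (40.8 ± 13.4 against 12.4 ± 3.12 CPM, -1.71, SE 0.24) and EGR2 (-1.42, SE 0.31) fell as well. Camera called the list (adjusted p = 4.96e-16), but not with an estimated correlation (adjusted p = 0.452). Of the 6, NR4A1 and EGR4 passed whichever library was left out, and 2 remained past the threshold without mutant replicate 2 (FOS at an adjusted p of 0.0516, list median -0.53) and 4 without mutant replicate 1. EGR2 did not pass by DESeq2 (adjusted p = 0.0602). The list's median was -0.23 without wild-type replicate 2.

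Transcripts of cytosolic ribosomal proteins, the structural proteins of the ribosome, were higher in the mutant libraries. All 44 members tested had a positive log2 fold change (median 0.32), 7 rose and 0 fell over all genes tested, and 29 rose adjusted over the list alone. RPL4 was 539 ± 54.4 CPM (SD, n = 2) in wild-type and 806 ± 65.0 CPM (SD, n = 2) in mutant libraries (0.58, SE 0.11, adjusted p = 0.00258). RPL5 was 229 ± 17.6 against 330 ± 22.9 CPM (0.53, SE 0.12), RPS27 185 ± 25.5 against 273 ± 32.7 CPM (0.56, SE 0.12) and RPS19 254 ± 30.7 against 372 ± 57.6 CPM (0.55, SE 0.12). The list took 1.14% and 1.05% of all counts in the wild-type libraries and 1.55% and 1.27% in mutant replicates 1 and 2. Camera called the list higher (adjusted p = 2.32e-23), but not with an estimated correlation (adjusted p = 0.5). Of the 7 risen members, 0 passed by edgeR without wild-type replicate 2, where the list's median was 0.26, and 1 without mutant replicate 1, where it was 0.16. Ribosomal protein genes have many processed pseudogenes, and how the authors counted reads shared with them is not given in the sources used here. Nuclear genes of the mitochondrial respiratory chain, also short and abundant, were not called. None of 29 passed by edgeR, DESeq2 or voom, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The median was -0.04 (camera adjusted p = 0.621), with ATP5MC3 at -0.22 (adjusted p = 0.434) and NDUFV1 at -0.20 (adjusted p = 0.517).

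Among 17 markers of migrating and newborn neurons, 2 rose, 0 fell and 15 did not pass (5 rose adjusted over the list alone). Of all 17, 12 had a higher and 5 a lower value in the mutant libraries (median 0.18), 1 of them lower at an unadjusted p under 0.05. CD24, a surface glycoprotein of immature neurons, was 222 ± 54.1 CPM (SD, n = 2) in wild-type and 345 ± 4.22 CPM (SD, n = 2) in mutant libraries (0.63, SE 0.13, adjusted p = 0.00926). DCX, a microtubule protein of migrating neurons, was 349 ± 55.3 against 493 ± 66.3 CPM (0.50, SE 0.12, adjusted p = 0.0241). Camera called the list higher (adjusted p = 1.93e-04), but not with an estimated correlation (adjusted p = 0.452). Neither gene passed without wild-type replicate 2 (adjusted p = 0.169 for CD24 and 0.286 for DCX) or without mutant replicate 2 (0.179 and 0.255). CD24 also did not pass without mutant replicate 1 (0.235). The list of cell cycle and progenitor genes was mixed, with 1 of 21 members risen and 1 fallen, also adjusted over the list alone (median -0.26, camera adjusted p = 0.162). MKI67, a marker of dividing cells, fell from 9.66 ± 0.853 to 4.85 ± 0.807 CPM (-0.99, SE 0.26, adjusted p = 0.0288). VIM, an intermediate filament of glial progenitors, rose from 113 ± 0.505 to 154 ± 23.4 CPM (0.44, SE 0.12, adjusted p = 0.0481). MKI67 passed only without wild-type replicate 1 and VIM only without mutant replicate 2 among the fits that left out 1 library. Neither passed by DESeq2 (adjusted p = 0.187 and 0.0746), and VIM did not by voom (0.0692) or with robust = FALSE (0.0591).

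Among mRNAs known as targets of FMRP, 2 of 57 members fell and 0 rose, also adjusted over the list alone (median -0.09). ARC, a cytoskeletal protein of active synapses that is also in the immediate early list, was 79.2 ± 28.5 CPM (SD, n = 2) in wild-type and 30.6 ± 0.341 CPM (SD, n = 2) in mutant libraries (-1.37, SE 0.23, adjusted p = 0.0192). BSN, a scaffold of the presynaptic active zone, was 241 ± 14.2 against 177 ± 10.3 CPM (-0.45, SE 0.12, adjusted p = 0.0290). Camera called the target list lower (adjusted p = 4.66e-04), but not with an estimated correlation (adjusted p = 0.568). At the preset correlation it was not called without mutant replicate 1 (adjusted p = 0.339) or wild-type replicate 2 (0.0714). ARC did not pass without mutant replicate 1 (adjusted p = 0.517) or mutant replicate 2 (0.358). BSN passed in none of the 4 fits that left out 1 library (adjusted p between 0.0511 and 0.223). None of the 22 partners and paralogs of FMRP passed by edgeR, DESeq2 or voom, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The median was 0.07 (camera adjusted p = 0.713), with STAU1 at 0.19 (adjusted p = 0.504) and PURA at -0.17 (adjusted p = 0.610).

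Synaptic and channel lists were slightly lower. Among 26 genes of synaptic vesicles and the active zone, 1 rose and 2 fell (1 and 4 adjusted over the list alone, median -0.19). The vesicle protein SYT4 rose (433 ± 69.3 to 612 ± 54.1 CPM, SD, n = 2 each; 0.50, SE 0.12, adjusted p = 0.0170). CPLX1, which clamps vesicle fusion (-0.61, SE 0.13, adjusted p = 0.00567), and BSN fell. Without wild-type replicate 2 or mutant replicate 2, neither SYT4 (adjusted p = 0.288 and 0.169) nor CPLX1 (0.106 and 0.128) passed. Among 24 genes of GABA signalling, 2 fell and 0 rose (4 fell adjusted over the list alone, median -0.16). They were the extrasynaptic receptor subunit GABRD (49.1 ± 15.7 to 26.0 ± 1.22 CPM, -0.92, SE 0.18) and the GABA-making enzyme GAD2 (142 ± 12.5 to 103 ± 7.77 CPM, -0.46, SE 0.12). Among 28 voltage-gated potassium channel genes, 1 fell and 0 rose, also adjusted over the list alone (median -0.22). It was KCNH5 (-0.56, SE 0.15, adjusted p = 0.0334), with KCNA1 next at -0.44 (adjusted p = 0.118). Camera called the vesicle (adjusted p = 4.66e-04), GABA (7.61e-04) and potassium channel lists (0.00762) lower. It called none with an estimated correlation (adjusted p = 0.452, 0.562 and 0.5). With 1 library left out, the vesicle median shrank furthest without wild-type replicate 2 (-0.09). The GABA and channel medians did so without mutant replicate 1 (-0.08 and -0.07). Without mutant replicate 1 the GABA (adjusted p = 0.0947) and channel lists (0.235) were not called, nor were the channels without wild-type replicate 2 (0.0649). GABRD and GAD2 passed only without wild-type replicate 1, and KCNH5 only without wild-type replicate 2, among those 4 fits. KCNH5 did not pass by DESeq2 (adjusted p = 0.106). None of 23 glutamate receptor genes passed by edgeR, DESeq2 or voom, or adjusted over the list alone (1 was higher and 5 lower at an unadjusted p under 0.05). The median was -0.08 (camera adjusted p = 0.148), with GRIN2A at -0.35 (adjusted p = 0.150) and GRIA4 at -0.35 (adjusted p = 0.185).

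Marker lists of the forebrain's neuron types were not called by camera, while single members changed. Among 21 markers of cortical excitatory neurons (median 0.10, camera adjusted p = 0.131), the transcription factor NEUROD6 rose (0.41, SE 0.11, adjusted p = 0.0469). The thyroid hormone binding protein CRYM fell (-0.55, SE 0.13, adjusted p = 0.0150), with 3 risen and 1 fallen adjusted over the list alone. NEUROD6 passed in none of the 4 fits that left out 1 library (adjusted p between 0.104 and 0.267) nor by voom (0.0526), and CRYM only without wild-type replicate 1. Among 23 interneuron markers, 1 fell and 0 rose, also adjusted over the list alone (median -0.07, camera adjusted p = 0.441). PVALB, a calcium buffer of fast-spiking cells, was 5.78 ± 1.03 CPM in wild-type and 2.00 ± 0.519 CPM in mutant libraries (SD, n = 2 each; -1.53, SE 0.34, adjusted p = 0.00974). It did not pass without mutant replicate 2 (adjusted p = 0.161) or by DESeq2 (0.0937), and NPY was next at 0.32 (adjusted p = 0.221). Among 16 hippocampal markers, 1 fell and 0 rose (3 fell adjusted over the list alone, median -0.23, camera adjusted p = 0.0543). It was the proteoglycan SPOCK1 (-0.50, SE 0.12, adjusted p = 0.0115), which did not pass without wild-type replicate 1 (0.209) or mutant replicate 1 (0.103), with LEF1 next at -0.83 (adjusted p = 0.0801). The hippocampal list was called lower without wild-type replicate 2 (adjusted p = 0.0217) and without mutant replicate 1 (0.0459). None of 23 striatal markers passed by edgeR, DESeq2 or voom, or adjusted over the list alone (3 were higher and 3 lower at an unadjusted p under 0.05). Their median of 0.02 and mean of -0.02 differed in sign (camera upward, adjusted p = 0.912), with RARB at 0.43 (adjusted p = 0.0835) and PPP1R1B at -0.32 (adjusted p = 0.192).

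Several markers of brain regions outside these forebrain parts were higher in wild-type replicate 1 than in the other 3 libraries. Among 12 tested markers of thalamus, hypothalamus, midbrain and hindbrain, 1 fell and 0 rose, also adjusted over the list alone. It was CBLN1, a synaptic organizer of cerebellar granule cells (12.5 ± 5.25 to 6.21 ± 0.391 CPM, SD, n = 2 each; -1.01, SE 0.26, adjusted p = 0.0333), with SLC6A3 next at -1.69 (adjusted p = 0.185). Camera called the list lower (median -0.83, adjusted p = 3.21e-06), but not with an estimated correlation (adjusted p = 0.5). The median was -1.2 without wild-type replicate 2. Without wild-type replicate 1 neither the list (median -0.10, adjusted p = 0.315) nor CBLN1 (adjusted p = 0.557) passed. CBLN1 also did not pass without mutant replicate 1 (adjusted p = 0.225) or mutant replicate 2 (0.271), by DESeq2 (0.175) or by voom (0.0672). Chosen after their values were seen, TCF7L2 was counted 1272, 139, 118 and 121 times, ZIC1 563, 173, 140 and 108 times and LHX9 115, 8, 11 and 16 times in wild-type replicates 1 and 2 and mutant replicates 1 and 2. In the choroid plexus and ependyma list, none of 15 members passed by edgeR, DESeq2 or voom, or adjusted over the list alone (1 was lower at an unadjusted p under 0.05). The median was 0.25 (camera adjusted p = 0.258), with FOLR1 at -0.72 (adjusted p = 0.354) and CLIC6 at 0.97 (adjusted p = 0.415). The plexus transcript TTR, also chosen after its values were seen, was counted 8, 89, 1244 and 87 times in the same order, so mutant replicate 1 stood apart. The choroid list was called higher without mutant replicate 2 (adjusted p = 7.34e-04) and without wild-type replicate 2 (0.0281).

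No passing member was found by edgeR, DESeq2 or voom in the remaining lists. Among 20 markers of meninges and fibroblasts, 2 were higher and 1 lower at an unadjusted p under 0.05, and 1 rose and 1 fell adjusted over the list alone. COL1A1 was at -0.74 (adjusted p = 0.0979 over all genes) and SLC13A4 at 0.60 (adjusted p = 0.112). Its median of -0.05 and mean of -0.01 were opposite in sign to the camera direction (adjusted p = 0.912). The list was called lower without wild-type replicate 1 (adjusted p = 0.00618) and higher without wild-type replicate 2 (0.00409). The 3 blood markers tested, too few for a list test, included ALAS2 at 0.95 (adjusted p = 0.435) and EPB42 at 0.80 (adjusted p = 0.520), with a median of 0.80 and 0 at an unadjusted p under 0.05 or adjusted over the list alone. Adjusted over the list alone, 0 members passed in the cholesterol synthesis, heat shock and hypoxia, and interferon response lists either. Of 19 genes of cholesterol synthesis, 1 was lower at an unadjusted p under 0.05 (IDI1 at -0.29, adjusted p = 0.310; HMGCS1 at -0.23, adjusted p = 0.381). The median of -0.02 was opposite in sign to the camera direction (adjusted p = 0.996). Of 23 heat shock and hypoxia genes, 3 were higher at an unadjusted p under 0.05 (HSPH1 at 0.37, adjusted p = 0.0981; HSPA8 at 0.31, adjusted p = 0.172). The list's median was 0.04 (camera adjusted p = 0.250). Of 15 interferon response genes, 2 were lower at an unadjusted p under 0.05 (among them IFI6 at -0.36, adjusted p = 0.356). The median was 0.00171 against a mean of -0.07 and a downward camera test (adjusted p = 0.344). In all, camera called 12 of the 26 lists at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.1. Correlated genes alone do not account for this loss, as the estimated setting also has only 2 degrees of freedom. The astrocyte correlation was estimated at -0.0263, below the preset 0.01, yet the list's unadjusted camera p rose from 1.72e-07 to 0.0292. Fry called 2, myelinating oligodendrocytes and endothelial cells. Some of the lists not called with all 4 libraries were called with 1 left out. Without mutant replicate 1, these were cortical excitatory neurons (higher, adjusted p = 0.0459), striatal neurons (higher, 0.0463), the cell cycle (lower, 0.0459) and the respiratory chain (lower, 0.00147). Glutamate receptors were called without mutant replicate 2 (lower, 0.0375) and the interferon response without wild-type replicate 2 (lower, 0.0399).

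**Figure D3:**
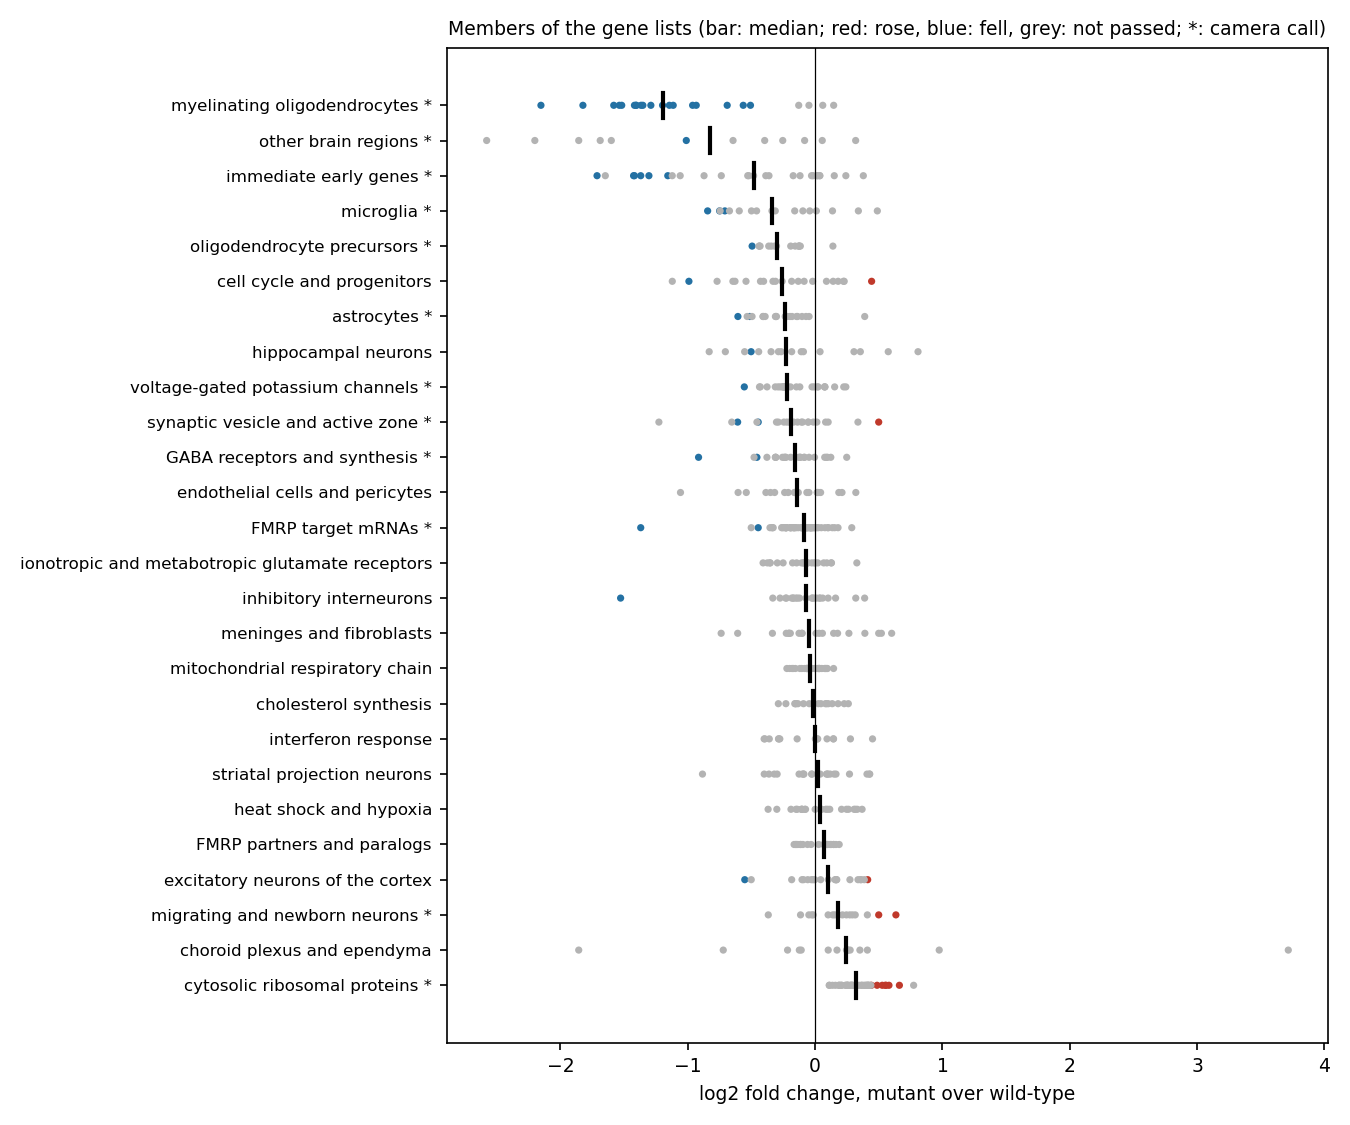
Log2 fold change of mutant over wild-type (horizontal axis) of each tested member of the 26 lists (vertical axis, ordered by median), with red for risen, blue for fallen and grey for members that did not pass, a black bar at each median and an asterisk where camera at the preset correlation called the list. Myelinating oligodendrocytes have the lowest median (-1.20) and cytosolic ribosomal proteins the highest (0.32).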

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

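The direction of all 378 changed genes was kept under every alternative in which they were tested. As all 378 had groups that did not overlap in CPM, this outcome was nearly fixed in advance and is no measure of stability. Lower genes made up between 63.6% and 72.4% of the calls under each alternative. Counts of changed genes stayed within 1.5 times of 378 with RLE (373) or upper-quartile scaling (370), limma-voom (348), robust = FALSE (371), a mean of at least 1 CPM (412) and without sex-linked genes (379). They moved further with DESeq2, run on all rows (244, of which 230 were among the 378), and without a low-count filter (633, all 378 included, with more genes tested by construction). The count also moved at an adjusted p of 0.1 (624, a looser threshold by construction). With 1 library left out the count ranged from 163 to 562, with between 139 and 255 of the 378 shared. The log2 fold change of FMR1 ranged from -0.0222 to 0.53 over those fits, and it passed in none of them. The replicate numbers do not pair the samples (correlation of same-numbered deviations across genes 0.0217), and with the number as a block 493 genes changed, all 378 among them. With an estimated correlation, where camera has only the 2 residual degrees of freedom, 0 of the 26 lists were called in place of 12. Fry, which tests another question, called 2. Risen ribosomal members, 7 in the main test, were 6 by DESeq2, 12 with the replicate block and 16 without a low-count filter. All 44 were tested in the main fit too, so testing more genes does not account for the calls they gained without the filter. Fallen immediate early members, 6 in the main test, were 6 by DESeq2, 9 with robust = FALSE and 14 without a low-count filter. Fallen markers of other brain regions, 1 in the main test, were 0 by DESeq2 and 3 with the replicate block or robust = FALSE. The hippocampal list, not called in the main test, was called with the replicate block (adjusted p = 0.042) and at a mean of at least 1 CPM (0.0095), and the cell cycle list without a low-count filter (0.0429). Over the named genes and list members, 868 values kept direction and side of the threshold across the alternatives, 132 lost the call, 14 gained one and 2 reversed. The reversals were ALAS2 (-0.15 to 1.58 over the fits with 1 library left out) and CLIC6 (-0.0496 to 1.57), neither of which had passed. Medians near 0 also reversed over those fits: FMRP partners (-0.00348 to 0.0651), striatal neurons (-0.157 to 0.129), meninges (-0.236 to 0.247, 0.00681 with the replicate block and 0.0164 with limma-voom), respiratory chain (-0.132 to 0.0958), cholesterol synthesis (-0.0925 to 0.0719), heat shock (-0.0448 to 0.0947) and interferon response (-0.304 to -0.0477, -0.0124 with the replicate block and -0.0267 with limma-voom). The choroid plexus median, 0.246 in the main test, was -0.0216 without mutant replicate 1 and 0.0976 to 0.177 in the other 3 fits. Apart from the changes built into the settings, the cause was not tested. At this depth and with 2 libraries per group, changes of 0.5 on the log2 scale are mostly missed, as the 28.4% recovered in simulated data shows.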

Other observations

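Of the tests given here, the added gene lists (nodes of Ranvier, neurofilaments, clock and TOP genes), the neighbour and identifier counts, and the tests of a single library, of an even loss of the lineage, of white matter and of short transcripts were chosen after the results they bear on were seen, although the values of the clock output and TOP genes themselves had not been looked at. Among 21 tested genes of nodes of Ranvier and axon-glia contact, 5 fell and 0 rose. Among them were CNTNAP1, which anchors the paranodal junction (-0.78), the cell adhesion molecules NFASC and CNTN2 (-0.54 each), and KCNAB2, a potassium channel subunit (-0.44). The median of the list was -0.23. Of 6 neurofilament and related filament genes, 3 fell and 1 rose: NEFH (-0.72), NEFL (-0.49) and NEFM (-0.48), the filaments of mature axons, fell, and INA, which is made earlier in development, rose (0.46). Both lists were put together with calls already seen, so no test of either list is given.

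Bare LOC identifiers stood out among the largest changes. They made up 14 of the 20 calls with a log2 change of at least 3 in size and 45 of the 358 other calls (Fisher's exact test, two-sided p = 2.25e-08). The calls were not matched on abundance, so low counts may account for part of this. LOC118150215 was counted 0 and 0 times in the wild-type and 18 and 20 times in the mutant libraries. LOC103788504 was counted 2 and 7 times in the wild-type and 557 and 438 times in the mutant libraries. Changed genes lay next to each other in the reference gene order in 10 pairs, against 8.11 on average for random genes (one-sided permutation p = 0.295). Of the 3 splits of the 4 libraries into 2 and 2, 1 gave as many changed genes as the real split, the real one itself with 378, and the highest other gave 0 by edgeR (324 genes at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom). With 3 splits no share under 0.05 can be reached. Each other split puts 1 wild-type and 1 mutant library on each side, so any group difference widens the spread within the sides. The 0 calls there are therefore no gauge of what chance alone would give.

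The lower myelin genes do not rest on 1 library, as at least 15 of the 19 fallen members kept their call whichever library was left out. The precursor list fell less than the myelin list, whose median lay below it by a difference of -0.89 (two-sided permutation of genes between the lists, p = 0.00868). The permutation takes genes, not libraries, as its units. Whether other cell types also make some of the precursor markers was not examined, and such markers would fall less under an even loss too. An even loss of the whole oligodendrocyte lineage therefore stays open. A smaller share of white matter in the dissected mutant pieces stays open, as the cortical excitatory list had a median of 0.10 with an adjusted camera p of 0.131. Later maturation of the mutant brains stays open as well: over 6 pairs of later and earlier genes the mean log2 ratio was lower by -0.15 in the mutant libraries, with 4 of 6 pairs lower, but the libraries' mean ratios (0.03 and 0.41 in wild-type, 0.06 and 0.08 in mutant) overlapped. An effect of the FMR1 mutation on oligodendrocyte maturation could give these values. It cannot be separated from litter, dissection or age within postnatal day 5, which the labels do not give.

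For the lower immediate early genes, of which 6 fell over all genes tested, the list's median stayed negative in each of the 4 fits that left out 1 library. It shrank most without wild-type replicate 2 (from -0.48 to -0.23). The estimated inter-gene correlation was 0.372, far above the preset 0.01. With the estimated correlation, and the 2 degrees of freedom that go with it, camera did not call the list with all 4 libraries (adjusted p = 0.452). How far the calls rest on 1 library stays open, as 4 of the 6 kept theirs without mutant replicate 1 and 2 without mutant replicate 2, at medians of -0.48 and -0.53. A different time of day at collection may account for part of it: the 7 clock output genes tested had a median of -0.28 (limma's camera, p = 0.00653, adjusted p = 0.0109 over the 5 added lists, and adjusted p = 0.276 with an estimated correlation). All 7 were lower, though NR1D1 was almost unchanged (-0.01), and 0 passed by edgeR. Clock genes of the opposite phase were not called either way (4 tested, median -0.01, adjusted p = 0.687 by limma's camera). Of these, 2 were lower and 2 higher: CLOCK at -0.22, NPAS2 at -0.05, BMAL1 at 0.02 and NFIL3 at 0.53. PER1, a clock gene in the immediate early list, was almost unchanged as well (-0.03). Handling before death and neuronal activity set by the genotype were not tested, and either could give the same values.

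For the higher ribosomal protein genes, camera called the list higher in each of the 4 fits that left out 1 library (largest adjusted p = 2.6e-08), with medians from 0.16 without mutant replicate 1 to 0.48 without mutant replicate 2. How far the calls rest on 1 library stays open, as 1 of the 7 risen members kept its call by edgeR without mutant replicate 1 and 0 did without wild-type replicate 2, against 6 in each of the other fits. The respiratory chain genes, also short and abundant, did not rise as much. Their median lay below that of the ribosomal list by a difference of -0.36 (permutation of genes between the lists, p = 1e-05, the smallest that 100000 resamples can give). That permutation treats genes as independent, though the estimated inter-gene correlation of the respiratory chain list was 0.71 as well. Its median also shifted with the library left out, to -0.13 without mutant replicate 1 and 0.10 without mutant replicate 2, as the ribosomal median did. A bias toward short abundant transcripts therefore stays open. A shared rise of mRNAs that begin with a terminal oligopyrimidine (TOP) tract, which are regulated together with growth signalling, is consistent with the added list, in which 13 TOP mRNAs outside the ribosome had a median of 0.23, at percentile 100 of 10000 random lists matched on expression (camera p = 1.4e-06, adjusted p = 3.49e-06, and adjusted p = 0.276 with an estimated correlation). The random lists were drawn gene by gene and matched on expression only. They reflect neither genes that vary together nor transcript length, so the percentile overstates the evidence. All 13 were higher and 0 passed by edgeR, and whether such a rise comes from the mutation or from another difference between the animals was not tested.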
